A study of Elephas maximus and Procavia capensis with 22 samples.

How the data were processed

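The series holds RNA sequencing of 18 libraries of Asian elephant cells and 4 of hyrax cells, in 11 lines or cultures of 2 libraries each. The authors deposited 3 tables of whole-number read counts per gene: 1 for 16 elephant libraries, 1 for the pre-iPSC culture and 1 for hyrax. RNA was extracted from whole cells and libraries were made by a commercial provider, per the labels' protocols. The tools Trim Galore 0.6.7, STAR, HISAT2, SAMtools, featureCounts, StringTie, Salmon, edgeR and DESeq2 3.18 are named per the submitters' processing notes. The sources used here do not give their roles, the genome build, the annotation release or whether counting used strand. Genes with near-identical copies or overlapping neighbours are therefore uncertain. Reads from transgenes carrying elephant coding sequences cannot be separated from reads of the cells' own genes.

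Groups were taken from the labels. Both labels of Eem6TH name the same column of the table, so its pair of columns was used as a group without numbering them. Names of the elephant libraries carry C1 or C2, which set the endothelial culture each iPSC line was compared with; nothing in the labels says that a line was made from that culture. The same names mark different factor constructs in C1 and C2 lines, and iPSC were grown in other media than endothelial cells, per the labels' protocols. Nothing says that the libraries of a line come from separate cultures. The p-values thus measure the spread between these libraries, which may be technical only. Leaving out 1 library of a pair assumes that the other varies like the rest.

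Elephant gene IDs were named through a RefSeq gene table of assembly mEleMax1, used for names only. Of 27135 IDs 25471 matched, 17868 carry a symbol and 9267 a placeholder. Of 21690 hyrax IDs 494 have no symbol, and 782 symbols stand on more than 1 ID. Library totals ran from 25815970 to 53794585 counts in elephant and from 14462973 to 24033733 in hyrax. A floor of 3 counts over a group corresponds to 0.0339 to 0.0533 CPM in elephant lines and to 0.0938 and 0.0707 CPM in Pla6T and pcF, on the TMM scale of the levels. Intervals and floors cover counting error only.

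Counts were filtered with filterByExpr by line and scaled by TMM. They were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, line as a factor without intercept, prior count 2). The 16 elephant libraries were fitted together, all 18 for the comparisons with pre-iPSC, and the 4 hyrax libraries apart, with 17174, 17235 and 14728 genes tested. Averages weight lines equally. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with an absolute log2 change of at least 1. TMM factors were 0.764 to 0.768 in the endothelial libraries and 1.03 to 1.15 in the other elephant libraries. The most abundant gene held 3.23 to 5% of counts in endothelial libraries.

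Lists of 21 functions were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 21 lists of a comparison. They cover reprogramming factors, core, naive and primed pluripotency, endothelial, fibroblast and mesenchymal, and epithelial genes, E2F and cell cycle, and senescence. The others are trophoblast, primitive and definitive endoderm (endoderm below), mesoderm, neuroectoderm, germ cell, blood, DNA methylation and Polycomb, glycolysis, interferon response, WNT targets, and TGF-beta and YAP targets. Some genes stand on more than 1 list, such as CDH1, EPCAM and HAND1. The genes named are the 6 delivered factors, up to 4 called members of each list described with the largest absolute change, and the 5 genes up and 5 down with the largest change. The last must have a symbol and a mean of at least 10 CPM in a compared group. Levels in CPM are given for a few of them; CDH5, whose level is given against the direction of its list, was picked after its values were seen. For the difference in response, the text keeps to the factors, the steepest genes and lists passing with both correlations. Some named genes, 1 of the lists and 2 comparisons within C1 are not reported here.

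Where a group had 0 counts, a bound was computed against 3 counts over the group. For 1 to 3 counts a ratio is given with its 95% interval from an exact binomial. The same ratio, of summed counts, is given for a called gene when a line in an averaged group had 3 counts or fewer, since the fitted average then rests on the prior count. In the difference in response such genes are given without a size. The rule for such lines was set after the data were seen. Comparisons, tests, lists, the naming rule and most alternatives were set before the data were examined. The alternatives were size factors (RLE), no low-count filter, a replicate block, DESeq2 1.42.0, no fold minimum, leaving out each library, leaving out lines, counts summed per line, and subsets of lines. Leaving out the whole line Eem6TH was added after the data were seen. The libraries' numbers do not pair the samples: the differences within pairs correlated at -0.067 to 0.24 over 28 pairs of lines, so the block served as an alternative only. Other splits of the samples into groups of the same sizes were refitted for the comparisons with at least 3 libraries a side.

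The pipeline was tested on simulated data with 100 genes changed 3-fold and 100 changed 8-fold. For iPSC against endothelial (16376 genes) edgeR recovered 96 and 99 of them with 1 false call. It recovered, for pre-iPSC against endothelial (15495 genes), 98 and 99 with 1, and, for hyrax (14448 genes), 95 and 100 with 2. The changed genes had at least 20 expected counts, with as many raised as lowered. Recovery was thus not tested for genes near the floor or for change in a large share of genes. Simulated lines of a group shared 1 mean per gene, so false calls from differences between lines were not tested either. The cutoffs of 10 and 0.1 CPM used in a test for mixed cells, the leaving out of delivered factors there, the 20 counts used in a test on gene models, and the lists of mucosal, HOX and imprinted genes, were set after levels were seen.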

Results

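RNA was sequenced from cells of the Asian elephant and of a hyrax, an African relative of elephants, and counted per gene in 22 libraries. They fall into 11 cultures or lines of 2 libraries each, 18 libraries from elephant and 4 from hyrax. The elephant set holds a pair of untreated endothelial cultures, emEC1 and emEC2, and 6 lines labelled as induced pluripotent stem cells (iPSC). Lines Ela6T, Ela6sh, Ela4T and Ela4sh had a chemical reprogramming step besides their transgenes and are called C1 here, as in the names of their libraries. Lines Eem6TH and Eem4TH had no chemical step and are called C2. A 6 in the name marks OSKMNL, the factors OCT4 (POU5F1), SOX2, KLF4, MYC, NANOG and LIN28A; a 4 marks OSKM, without NANOG and LIN28A. T marks SV40 T antigen, a viral oncoprotein, and Ela6sh and Ela4sh carried the factors without it. A further elephant culture, pre-iPSC, had the chemical step alone, is labelled as partially reprogrammed and came in a separate table. In hyrax, line Pla6T carried the elephant OSKMNL factors and T antigen, and pcF were untreated fibroblasts. Library totals ran from 25815970 counts (Ela4sh 1) to 53794585 (Ela6sh 1) in elephant and from 14462973 to 24033733 in hyrax. Over the 2 libraries of an elephant group, 3 counts amount to between 0.0339 and 0.0533 CPM, the unit of counts scaled to the library total times its TMM factor.

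Changes are log2 fold changes ± standard error, and a gene was called when edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05 with a log2 change of at least 1 in size. Where 1 group had 0 counts, the change is a lower bound against 3 counts in that group. With 1 to 3 counts, or with a line of the group at 3 counts or fewer, it is a ratio of summed counts with its 95% counting interval. Gene lists were fixed beforehand and tested as sets with camera at a preset correlation of 0.01. The number of members called when adjusted over the list alone is given where it differs from that over all genes. Every group had n = 2 libraries, and levels are mean CPM ± SD. Reads from the elephant transgenes cannot be separated from those of the cell's own copies. Levels of a factor may thus include both in a line that carried it. By the labels the OSKM lines carried no NANOG or LIN28A transgene, and pre-iPSC and the untreated cultures carried no factor.

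What reprogrammed lines of either route gained and lost was asked by setting the 12 iPSC libraries against the 4 endothelial libraries, with C1 lines also set against emEC1 and C2 lines against emEC2. In the pooled comparison 3268 genes rose and 2935 fell, of 17174 tested. LIN28A, POU5F1 and SOX2 had 0 counts in the endothelial cultures and were at least 3580-fold, at least 1930-fold and at least 41.4-fold higher in the iPSC lines. NANOG rose by 1.55 ± 0.36 (adjusted p = 0.000484). MYC fell by 2.09 ± 0.049 (adjusted p = 3.54e-20), while KLF4 (0.04 ± 0.058, adjusted p = 0.549) was not called. The call of POU5F1 was lost without Ela4sh 2, whose line then had 0 counts of it (fitted change 9.05). Among the steepest rises were CDH1, the adhesion molecule of epithelia, with a ratio of 72700 (13100 to 2870000), and NPNT, TMPRSS2 and SLC6A14, at least 5600-fold, 3150-fold and 4850-fold higher. SCGB1A1, a secreted airway protein, was at least 37100-fold higher, a call lost without library D_2 of Eem6TH (fitted change 13.68). This rise of SCGB1A1 lay in C1, at 1290 to 1800 CPM against 0.0873 ± 0.12 in Eem6TH and 0.8 ± 0.35 in Eem4TH. Among the steepest falls were COL3A1 (-13.27 ± 0.048) and MAGEL2, at least 8400-fold lower. DCN, MXRA5 and MEDAG were lower with ratios of 15600 (11800 to 21100), 3570 (3090 to 4160) and 3240 (2250 to 4830).

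**Figure D1:**
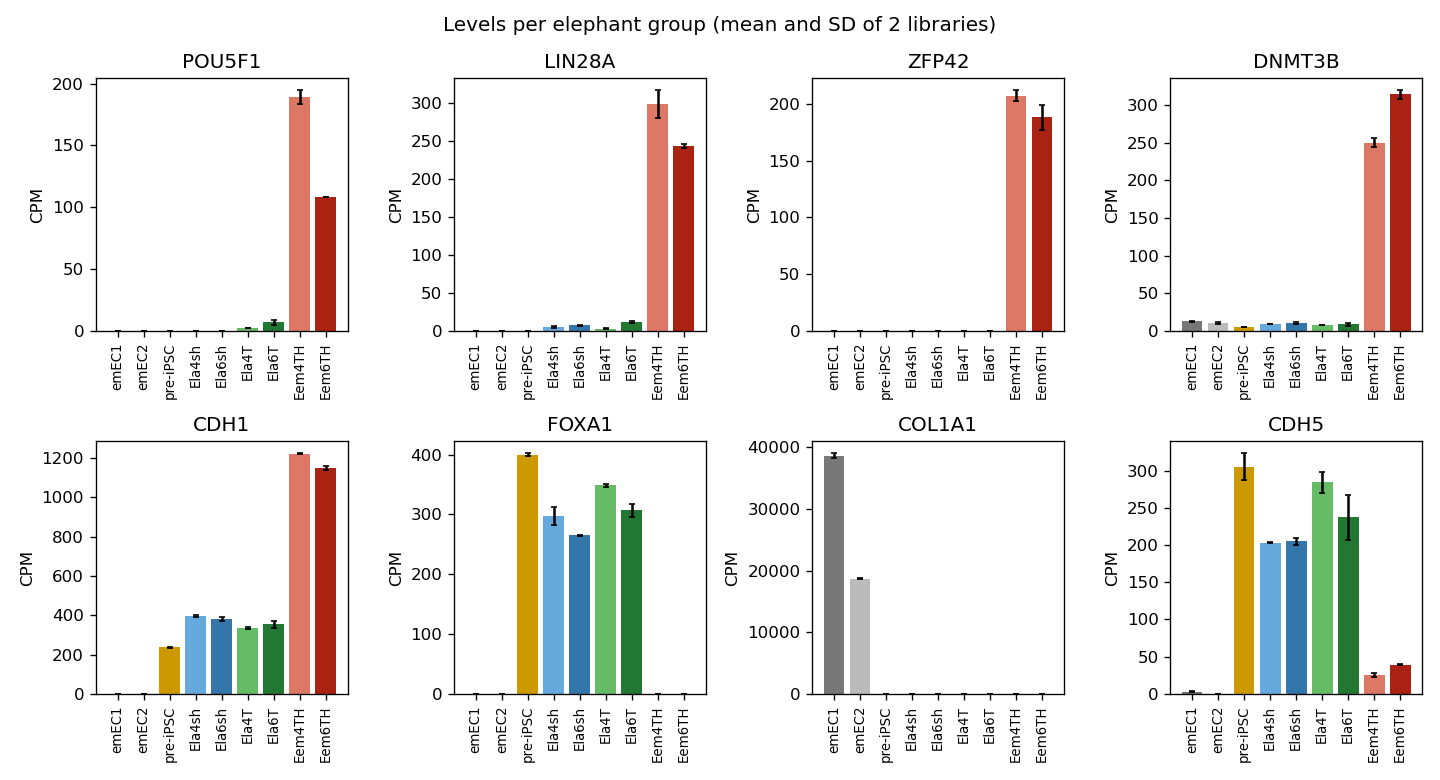
Bars give the mean CPM of 8 genes in each of the 9 elephant cultures and lines, with error bars for the SD of 2 libraries. POU5F1 stands at 189 and 108 CPM in the C2 lines Eem4TH and Eem6TH and at 6.85 CPM or less elsewhere, while FOXA1 stands at 265 to 400 CPM in the C1 lines and pre-iPSC and under 0.1 CPM elsewhere.

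The C1 and C2 lines shared part of this change. Of 17174 genes, 1923 rose in both against the endothelial culture matched by name (874 expected if unrelated) and 1712 fell in both (625 expected), while 774 were called in opposite directions (1486 expected). These comparisons share no library. The untreated cultures correlated at r = 0.968 across genes, so shared change may include loss of what both had in common. Both epithelial and mesenchymal lists moved in each. In C1, 20 of 21 epithelial genes rose and 1 fell (adjusted p = 4.41e-15, 0.00318 with an estimated correlation), with EPCAM at a ratio of 9040 (2500 to 74600) and CRB3 at least 513-fold higher. In C2, 21 of 21 rose (adjusted p = 4.55e-25, 0.000346 with an estimated correlation), with CDH1 at least 22200-fold and ESRP1 at least 3400-fold higher. Of 31 fibroblast and mesenchymal genes, 27 fell and 2 rose in C1 and 30 fell and 1 rose in C2 (adjusted p = 9.6e-30 and 1.96e-35, 0.00214 and 0.000228 with an estimated correlation). DCN and COL6A2, proteins of connective tissue, were lower in C1 with ratios of 42300 (25200 to 77400) and 59000 (37300 to 99600), and COL3A1 (-13.59 ± 0.086) fell in C2, where FAP was at least 10300-fold lower. All 15 targets of TGF-beta and YAP fell in either set (adjusted p = 2.57e-21 and 1.69e-19, 0.00273 and 0.000195 with an estimated correlation), including AXL (-10.94 ± 0.06 in C1 and -7.58 ± 0.062 in C2). Trophoblast genes rose in part, 9 of 16 up and 3 down in C1 (adjusted p = 0.0109, 0.0447 with an estimated correlation) and 10 up and 1 down in C2 (adjusted p = 2.66e-05, 0.00538 with an estimated correlation).

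Which pluripotency genes were on differed between C1 and C2. Against emEC2, 22 of 24 core pluripotency genes rose and 2 fell in C2 (adjusted p = 1.5e-09, 0.00119 with an estimated correlation). There LIN28A, ZFP42 and POU5F1 were at least 5060-fold, 3700-fold and 2780-fold higher, and SOX2 at least 7.68-fold. Against emEC1, 12 rose, 1 fell and 11 were not called in C1 (adjusted p = 0.0885). In C1, LIN28A was at least 130-fold, SALL4 at least 107-fold, POU5F1 at least 42.8-fold and SOX2 at least 27.4-fold higher. The counts of POU5F1 in C1 lay mainly in the T antigen lines, at 2.13 ± 0.067 CPM in Ela4T and 6.85 ± 1.7 in Ela6T, and close to the floor of 3 counts in Ela4sh (0.0339 ± 0.048) and Ela6sh (0.0492 ± 0.02). KLF4 rose in C1 (1.35 ± 0.08) and fell in C2 (-2.62 ± 0.093), MYC fell in both (-1.50 ± 0.065 and -3.45 ± 0.082), and NANOG rose in both (1.48 ± 0.57, adjusted p = 0.0231, and 2.53 ± 0.4, adjusted p = 7.7e-06). Within C1 the rise of NANOG lay mainly in Ela6T (3.39 ± 0.71 CPM), with 0.375 ± 0.13 in Ela4T, 0.0868 ± 0.021 in Ela4sh and 0.202 ± 0.063 in Ela6sh against 0.14 ± 0.1 in emEC1. NR0B1, counted among naive pluripotency genes, rose in C2 (8.72 ± 0.27) and was lower in C1 with a ratio of 1030 (284 to 8550). The de novo DNA methyltransferase DNMT3B rose in C2 (4.77 ± 0.11), as did VRTN (at least 298-fold) and TFCP2L1 (at least 551-fold, and 7.60 ± 0.3 in C1).

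Single genes rose steeply in C1. SCGB1A1, the stem cell and epithelial surface protein PROM1, the fatty acid carrier FABP4 and the gastric TFF1 were at least 28100-fold, 28000-fold, 26300-fold and 6370-fold higher than in emEC1. The endoderm regulators FOXA1 and HNF4A were at least 5790-fold and 977-fold higher, and 6 of 11 endoderm genes rose and 1 fell (adjusted p = 0.0308, and 0.083 with an estimated correlation). CDX2, shared by trophoblast and intestine, was at least 1210-fold higher in C1 and at least 258-fold in C2, and LGR5, a WNT target of intestinal stem cells, at least 3340-fold and 22.4-fold. Of 14 WNT targets 7 rose and 1 fell in C1 (adjusted p = 0.0109, 0.0447 with an estimated correlation). PRSS35 and FMOD were at least 16300-fold and 16900-fold lower in C1, and MXRA5 at least 135000-fold lower. In C2 the endocytic receptor LRP2 was at least 4200-fold higher, ITGB8 at least 29400-fold lower and ESM1 at least 11100-fold lower, with THBS2 lower at a ratio of 4530 (2300 to 10500).

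Endothelial and interferon genes separated the C1 from the C2 responses. Both lists also differed between the untreated cultures, as given below, so part of this may lie in the cultures. Of 31 endothelial genes, 20 fell and 5 rose in C1 (adjusted p = 0.00034, 0.00848 with an estimated correlation), with THBD down (-8.63 ± 0.17) and EMCN, PECAM1 and CD34 lower at ratios of 1360 (740 to 2840), 1100 (742 to 1730) and 204 (131 to 336). In C2, 15 rose and 12 fell, so the median was positive while the test pointed down (adjusted p = 0.576). CDH5, the cadherin of endothelial junctions, did not follow the list: it rose in C2 (8.16 ± 0.25) and stood at 203 to 284 CPM in C1 lines against 2.89 ± 0.5 in emEC1. ECSCR also rose in C2, with a ratio of 513 (142 to 4240), while LMO2 (-8.18 ± 0.12) fell. All 17 interferon response genes fell in C1 (adjusted p = 1.97e-12, 0.00511 with an estimated correlation), among them IFI44L, with a ratio of 1800 (913 to 4180), USP18 (-6.88 ± 0.15) and ISG15 (-6.23 ± 0.15). In C2, 8 rose and 3 fell (adjusted p = 0.429), with IFIT3 up (4.03 ± 0.3) and IFI44 lower with a ratio of 45.6 (24.2 to 96.7).

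Over all 12 iPSC libraries the lists that passed were fibroblast and mesenchymal (30 of 31 down, 1 up, adjusted p = 1.68e-23), epithelial (20 of 21 up, 6.39e-15) and TGF-beta and YAP targets (15 of 15 down, 6.39e-15), each at 0.00714 with an estimated correlation. Core pluripotency (13 of 24 up, 1 down) and endothelial (15 of 31 down, 5 up) both had adjusted p = 0.024, and adjusted p = 0.0531 with an estimated correlation. Trophoblast (9 of 16 up, 3 down, adjusted p = 0.0137) and interferon response (14 of 17 down, adjusted p = 0.00176) also had adjusted p = 0.0531 with an estimated correlation. Those not passing were reprogramming factors (4 of 7 up, 1 down, adjusted p = 0.601), naive pluripotency (6 of 11 up, 3 down, 0.161), germ cell (4 of 8 up, 1 down, 0.161), WNT targets (8 of 14 up, 3 down, 0.204) and E2F and cell cycle (2 of 33 up, 0.268). Endoderm (5 of 11 up, 1 down) and mesoderm (2 of 9 up, 4 down) had adjusted p = 0.592. Blood (3 of 8 up, 2 down) and DNA methylation and Polycomb (2 of 13 up, 1 down) had 0.72, and glycolysis (2 of 16 up, 1 down) had 0.947. For primed pluripotency (3 of 10 up, 2 down, 0.654) the median and mean were positive and the test pointed down. Senescence (2 of 11 up, 3 down, 0.72) and neuroectoderm (2 of 9 up, 2 down, 0.848) had a positive median and a test pointing down. The same number of genes passed when adjusted over the list alone in each of the 21. Single members of lists that did not pass still rose, such as KIT of the germ cell list (8.12 ± 0.11). HAND1, on the mesoderm and trophoblast lists, rose as well (7.42 ± 0.15).

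**Figure D2:**
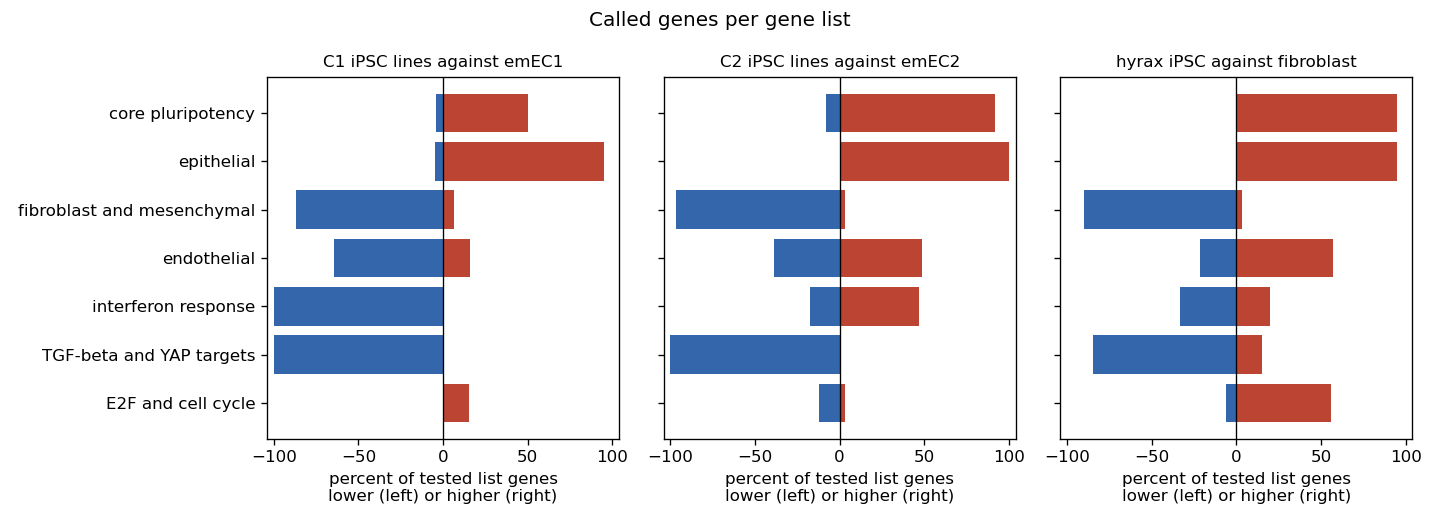
For 7 gene lists, bars give the percent of tested genes called higher or lower in C1 lines against emEC1, in C2 lines against emEC2 and in hyrax Pla6T against fibroblasts. TGF-beta and YAP targets were called lower in 15 of 15 genes in both elephant sets, and core pluripotency genes were called higher in 12 of 24 in C1 and 22 of 24 in C2.

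Set singly against the culture matched by name, the C1 lines gave 3574 genes up and 3119 down in Ela6T, 3554 and 3154 in Ela6sh, 3535 and 3052 in Ela4T, and 3447 and 3115 in Ela4sh. Eem4TH gave 4085 up and 3271 down, and Eem6TH 4361 and 3166. Across genes, which are not independent replicates, C1 lines correlated with each other at r = 0.988 to 0.995, with pre-iPSC at 0.965 to 0.972 and with C2 lines at 0.8 to 0.814. They correlated with emEC1 at 0.789 to 0.79 and with emEC2, the culture not matched by name, at 0.8 to 0.804.

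**Figure D3:**
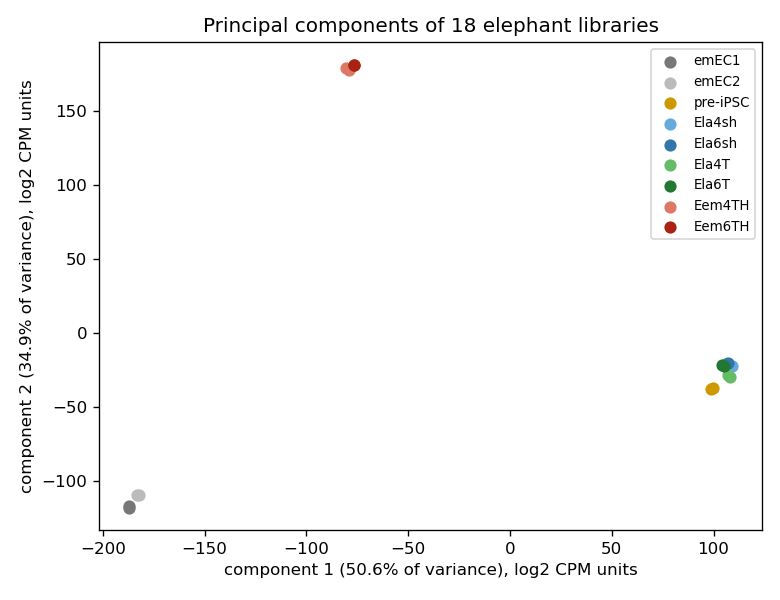
Each point is 1 of the 18 elephant libraries placed on the first and second principal components of log2 CPM, which hold 50.6% and 34.9% of the variance. C1 lines and pre-iPSC lie together, apart from the C2 lines and from the endothelial cultures.

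What NANOG and LIN28A added to OSKM was asked within each route. In C1, OSKMNL against OSKM gave 53 genes up and 18 down. LIN28A rose (1.22 ± 0.094, adjusted p = 4.72e-07) and so did NANOG (2.21 ± 0.42, adjusted p = 0.00245), the latter not called without Ela6sh 1 (2.0). POU5F1 (1.02 ± 0.66, adjusted p = 0.373), KLF4 (-0.32 ± 0.063), MYC (-0.05 ± 0.065) and SOX2 (0.91 ± 0.5, and -0.24 without Ela6sh 1) were not called. RAB25, a trafficking GTPase of epithelia, rose (1.27 ± 0.2; -0.24 for Ela6sh against Ela4sh), and so did ENPP3 (1.33 ± 0.13) and the granule protein SCG2 (1.01 ± 0.14). SCG2 lay under the fold minimum without Ela4T 1 (0.91), Ela6T 1 (1.00) or Ela4sh 2 (0.98). CRMP1 (-1.89 ± 0.19), FCGBP (-1.85 ± 0.16) and TFF3 (-1.20 ± 0.085), products of neurons and of goblet cells, fell. Core pluripotency had 2 of 24 genes up, 3 adjusted over the list alone (adjusted p = 0.0469, and 0.176 with an estimated correlation), and reprogramming factors 2 of 7 (adjusted p = 0.0728). Epithelial genes had 1 of 21 up (adjusted p = 2.79e-06, and 0.0754 with an estimated correlation). DNA methylation and Polycomb genes had edgeR and DESeq2 calls in 0 of 13, with 8 under an unadjusted p of 0.05 (adjusted p = 0.0342, and 0.37 with an estimated correlation). Naive pluripotency also had 0 calls by either tool in 11 genes, 4 under an unadjusted p of 0.05, with a mean above 0 and a test pointing down (adjusted p = 0.0342, and 0.176 with an estimated correlation). The number of genes called was 45 without Ela6sh 1 and 121 without Ela6T 1. It was 215 for Ela6T against Ela4T and 4 for Ela6sh against Ela4sh.

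In C2, OSKMNL against OSKM gave 761 genes up and 279 down. Each factor set is a single line here (Eem6TH and Eem4TH), so its effect cannot be told apart from a difference between lines. None of the 7 reprogramming factors was called by edgeR or DESeq2. POU5F1 (-0.81 ± 0.098, adjusted p = 3.95e-06), LIN28A (-0.30 ± 0.08) and KLF4 (-0.64 ± 0.14) stayed under the fold minimum, as did MYC (-0.32 ± 0.11), SOX2 (0.60 ± 0.77) and NANOG (-0.00 ± 0.36). Of the factors, 4 had an unadjusted p under 0.05 (list adjusted p = 0.043, and 0.133 with an estimated correlation). The pluripotency regulators PRDM14 (1.78 ± 0.21), SALL1 (1.10 ± 0.17) and NR0B1 (1.75 ± 0.14) rose, and KLF5 fell (-1.15 ± 0.073). TGF-beta and YAP targets fell as a set, 4 of 15 down and 1 up (adjusted p = 5.84e-06, 0.0122 with an estimated correlation). Among them were CCN2 (-1.77 ± 0.079), CCN1 (-1.21 ± 0.087) and AXL (-1.09 ± 0.11). Collagens fell, COL3A1 (-5.40 ± 0.33) and COL1A2 (-3.44 ± 0.23), within a list that had 5 up and 6 down of 31, and 7 down adjusted over the list alone. PECAM1 (1.94 ± 0.19), the growth factors BMP4 (2.83 ± 0.2) and IGF2 (4.06 ± 0.22) and PDGFRA (1.66 ± 0.14) rose. GRIN2A rose with a ratio of 2180 (604 to 18000), beside TRIML2 (4.08 ± 0.21) and GPNMB (2.98 ± 0.12). STPG1 (-3.61 ± 0.35), UROC1 (-2.93 ± 0.3), DNAH12 (-2.84 ± 0.27), SNX4 (-2.69 ± 0.065) and NPPB (-2.52 ± 0.23) fell. Mesoderm had 2 of 9 up, 4 adjusted over the list alone (adjusted p = 0.00234, and 0.0847 with an estimated correlation). Interferon response had 2 of 17 down, 3 adjusted over the list alone (adjusted p = 0.0169, and 0.133 with an estimated correlation), with USP18 (-2.06 ± 0.33) and RSAD2 (-1.57 ± 0.3) lower. Senescence had 1 of 11 up and 1 down (adjusted p = 0.0287, and 0.115 with an estimated correlation).

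How T antigen lines with and without the chemical step differed was asked by setting Ela6T and Ela4T against Eem6TH and Eem4TH. In C1, 3623 genes were higher and 3763 lower. Core pluripotency genes were lower in C1, 21 of 24 down and 1 up (adjusted p = 3.72e-13, 0.000588 with an estimated correlation). ZFP42, UTF1, PRDM14 and DPPA4, transcripts of pluripotent cells, were at least 9080-fold, 3470-fold, 823-fold and 299-fold lower, with 0 counts in the C1 T antigen lines. On average POU5F1 (-5.21 ± 0.094), LIN28A (-5.49 ± 0.077) and NANOG (-1.19 ± 0.28, adjusted p = 0.000595) were lower in C1. SOX2 (2.21 ± 0.49, adjusted p = 0.000397), KLF4 (4.26 ± 0.08) and MYC (2.54 ± 0.073) were higher. For NANOG this held for Ela4T (0.281 and 0.47 CPM) but not for Ela6T (3.89 and 2.89), against 2.44 to 2.72 in C2. SOX2 lay mainly in Ela6T (4.94 and 3.31 CPM), with 0.674 and 0.999 in Ela4T and 0.262 to 0.57 in C2. LIN28B was at least 533-fold lower. NR0B1 was lower with a ratio of 3850 (1070 to 31800), and DNMT3B by -5.06 ± 0.079, in a list of DNA methylation and Polycomb genes with 7 of 13 down (adjusted p = 0.00319, and 0.198 with an estimated correlation). Epithelial genes were lower in C1, 12 of 21 (adjusted p = 3.98e-12, 0.00669 with an estimated correlation), among them the claudins CLDN6 (-9.77 ± 0.13) and CLDN7 (-6.23 ± 0.068), and RAB25 (-6.32 ± 0.14). Endoderm genes were higher in C1, 8 of 11 up and 1 down (adjusted p = 2.09e-05, 0.00833 with an estimated correlation), with FOXA2 (6.40 ± 0.21) and with FOXA1 and TTR at ratios of 7770 (3570 to 21200) and 1410 (389 to 11600).

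In the same comparison TGF-beta and YAP targets were lower in C1, 9 of 15 down and 4 up (adjusted p = 0.000133, 0.0106 with an estimated correlation), with ANKRD1 (-9.78 ± 0.094), AXL (-3.71 ± 0.14), CALD1 (-3.66 ± 0.054) and MYL9 (-3.49 ± 0.061). WNT targets had 9 of 14 up and 2 down (adjusted p = 0.0055, and 0.13 with an estimated correlation), LGR5 at 7.82 ± 0.11 and CDX1 lower with a ratio of 292 (134 to 797). E2F and cell cycle genes had 6 of 33 down and 1 up (adjusted p = 0.0155, and 0.198 with an estimated correlation), the exception being E2F2 (4.28 ± 0.058), while MYBL2 fell (-1.82 ± 0.048). Glycolysis had 6 of 16 up (adjusted p = 0.0189, and 0.289 with an estimated correlation), led by PFKP (1.53 ± 0.034), and mesoderm 3 of 9 up and 1 down (adjusted p = 0.0236, and 0.198 with an estimated correlation). Endothelial genes, 18 of 31 lower and 7 higher, did not pass as a set (adjusted p = 0.171), with ECSCR at least 839-fold lower and CLEC14A at least 71.9-fold higher. CXCL8 was higher with a ratio of 2380 (659 to 19700). CLCA1, FABP1 and SSTR1 were at least 23500-fold, 13400-fold and 3710-fold higher, beside the gastric mucin MUC5AC and FABP4, with ratios of 10100 (4920 to 25200) and 11600 (7490 to 18900). MPZL2 and ARHGAP36 were at least 3610-fold and 1820-fold lower. The routes differ also in the C1 or C2 of their library names and in factor construct, so these values belong to the route and to what goes with it.

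Whether the change from the endothelial culture matched by name differed between C1 and C2 was tested as a difference in response, C1 T antigen lines minus emEC1 against C2 lines minus emEC2. It was larger in C1 for 3060 genes and smaller for 3118. Larger and smaller are signed here, so a gene that fell further in C1 than in C2 counts as smaller. KLF4 (4.15 ± 0.13) and MYC (2.14 ± 0.12) differed, and NANOG did not pass (0.46 ± 0.7, adjusted p = 0.615; -0.12 without emEC1 1). POU5F1, SOX2 and LIN28A had 0 counts in both cultures, so edgeR's test says nothing on them. Under DESeq2, 2 named genes that edgeR did not call were called in this comparison. No size is given for genes with 3 counts or fewer in a line or culture compared. Among these the response of IL33 (adjusted p = 1.73e-14) and of the neuropeptide genes TAC1 (3.04e-10) and PENK (2.11e-16) was larger in C1. FOXA1 and FABP4 were not called without emEC2 1 (fitted changes 14.15 and 14.14). It was smaller for SLC7A3 (3.62e-20), NR0B1 (3.79e-17), FOLR1 (1.5e-05) and VSIG2 (1.09e-07). MPZL2 was not called without emEC1 2 (fitted change -14.38). Endothelial genes (20 of 31 smaller, 4 larger, adjusted p = 0.00295, 0.0403 with an estimated correlation) included CD34 (adjusted p = 1.27e-14) and TIE1 (2.09e-05). Interferon response genes (14 of 17 smaller, adjusted p = 3.36e-10, 0.00928 with an estimated correlation) included IFIT3 (-9.42 ± 0.37), ISG15 (-9.33 ± 0.33) and HERC6 (-7.23 ± 0.33). TGF-beta and YAP targets (9 of 15 smaller, 3 larger) had adjusted p = 0.00414, and 0.05 with an estimated correlation. E2F and cell cycle (7 of 33 larger, 1 smaller, adjusted p = 0.018) had adjusted p = 0.254 with an estimated correlation. DNA methylation and Polycomb (5 of 13 smaller, 0.0195) and glycolysis (8 of 16 larger, 1 smaller, 2.6e-05) had adjusted p = 0.341 and 0.187 with an estimated correlation.

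How far the untreated cultures differed was asked with emEC1 against emEC2, in which 1600 genes were higher and 1071 lower in emEC1. Interferon response genes were higher in emEC1, 15 of 17 (adjusted p = 1.14e-22, 0.000363 with an estimated correlation). IFI44L had a ratio of 1430 (395 to 11800), and HERC6 (6.36 ± 0.28), the interferon regulator IRF7 (5.73 ± 0.2), IFIT3 (5.73 ± 0.31) and the antiviral BST2 (6.92 ± 0.41) were higher. Replication genes were lower in emEC1, 13 of 33 of the E2F list (adjusted p = 9.48e-21, 0.00349 with an estimated correlation), among them RRM2 (-2.65 ± 0.054), CDC6 (-1.81 ± 0.13), MCM4 (-1.58 ± 0.064) and GINS2 (-1.55 ± 0.096). Endothelial genes were higher in emEC1, 12 of 31 and 1 lower (adjusted p = 0.000735, 0.0317 with an estimated correlation), with NOS3 at least 14.7-fold, CLEC14A at least 6.53-fold, TAL1 at a ratio of 56.8 (15.4 to 474) and CDH5 at 4.71 ± 0.44. Fibroblast and mesenchymal genes had 10 of 31 up and 1 down (adjusted p = 0.00073, and 0.0751 with an estimated correlation), with POSTN (3.98 ± 0.3) and COL6A1 (1.77 ± 0.073). Glycolysis had 1 of 16 up and 1 down (adjusted p = 0.00073, and 0.36 with an estimated correlation). CDH6 (6.37 ± 0.35) and PRELP (6.33 ± 0.54) were higher. RIT2 was at least 210-fold lower, LCN2 and GREM1 lower with ratios of 602 (166 to 4970) and 331 (91.1 to 2730), and LIPG (-6.68 ± 0.17) and CRACR2A (-6.54 ± 0.39) lower. NANOG (-1.65 ± 0.64, adjusted p = 0.0356) lost its call without emEC1 1 (-1.07), emEC2 1 (-1.44) or emEC2 2 (-1.85).

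What the chemical step alone had changed was asked with pre-iPSC against both endothelial cultures, with 3663 genes up and 2993 down of 17235. The pre-iPSC libraries came in their own table, so a difference between tables cannot be separated from the step. KLF4 rose (2.29 ± 0.07). LIN28A was at least 3.45-fold higher, but this rests on 2 and 4 counts in the pre-iPSC libraries (0.0576 and 0.128 CPM), close to the floor. POU5F1 (2.35 ± 1.8, adjusted p = 0.258), NANOG (0.54 ± 0.5, adjusted p = 0.338) and MYC (-0.05 ± 0.073) were not called. SOX2 was not called either (adjusted p = 0.0906), though it was without pre-iPSC 2 (fitted change 5.01). Epithelial genes rose, 18 of 21 up and 1 down (adjusted p = 4.05e-11, 0.00467 with an estimated correlation), with CDH1 at a ratio of 27100 (4860 to 1070000) and EPCAM at 3190 (1620 to 7380). Fibroblast and mesenchymal genes fell, 28 of 31 down and 2 up (adjusted p = 8.86e-22, 0.000263 with an estimated correlation), PRRX1 at least 3010-fold and COL1A2 at -12.83 ± 0.14. Targets of TGF-beta and YAP fell in 15 of 15 (adjusted p = 1.44e-14, 0.000263 with an estimated correlation), AXL at least 18300-fold lower and ANKRD1 at -12.10 ± 0.15. Interferon response genes fell in 16 of 17 (adjusted p = 2.01e-05, 0.0127 with an estimated correlation), ISG15 at -4.40 ± 0.31. Trophoblast had 7 of 16 up and 1 down (adjusted p = 0.00325, 0.0296 with an estimated correlation), with CDX2 at least 2480-fold and GATA3 at 12.95 ± 0.12.

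Core pluripotency genes did not pass as a set in pre-iPSC (9 of 24 up and 2 down, 8 up adjusted over the list alone, adjusted p = 0.242), with SALL4 at least 211-fold higher and SALL1 down (-9.13 ± 0.24). Naive pluripotency (7 of 11 up, 3 down) and endoderm (6 of 11 up, 2 down) both had adjusted p = 0.023, and adjusted p = 0.0901 and 0.0604 with an estimated correlation. WNT targets (8 of 14 up, 2 down) had adjusted p = 0.0171, and 0.0604 with an estimated correlation. Endothelial genes, 14 of 31 down and 6 up (15 down adjusted over the list alone), had adjusted p = 0.0735. PECAM1 and EMCN were at least 1420-fold and 839-fold lower while CDH5 rose (9.08 ± 0.13). FOXA1 rose with a ratio of 22700 (6290 to 188000), SCGB1A1, TFF1 and HTR7 were at least 85000-fold, 14700-fold and 12000-fold higher, and VIP and FABP4 had ratios of 91700 (25400 to 757000) and 75000 (20800 to 620000). PRSS35, FIBIN and PTK7 were at least 5320-fold, 3870-fold and 3350-fold lower.

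What the transgenes added to the chemical step was asked with the 8 C1 iPSC libraries against pre-iPSC, in which 1130 genes were higher and 1099 lower in the iPSC lines. Here too a difference between tables cannot be separated from the transgenes. LIN28A (5.98 ± 0.27) and SOX2 (3.74 ± 0.91, adjusted p = 0.00154) were higher, and POU5F1, counted mainly in Ela4T and Ela6T, had a ratio of 147 (26.3 to 5830), a call lost without Ela4sh 2 (fitted change 3.59). MYC was lower (-1.26 ± 0.063), and KLF4 (-0.89 ± 0.061) and NANOG (0.11 ± 0.49, adjusted p = 0.903) were not called. Epithelial genes were higher, 7 of 21 (adjusted p = 0.000459, 0.0458 with an estimated correlation), with MARVELD3 (3.26 ± 0.43), RAB25 (2.97 ± 0.35), ST14 (2.60 ± 0.19) and GRHL2 (2.11 ± 0.12). TGF-beta and YAP targets were lower, 5 of 15 down and 1 up (adjusted p = 0.000638, 0.025 with an estimated correlation). CCN2 (-3.51 ± 0.057) and CCN1 (-2.46 ± 0.059) fell and AXL was at least 9.99-fold higher. Naive pluripotency genes tested lower, 2 of 11 down and 1 up (adjusted p = 0.00605, 0.0453 with an estimated correlation), with SUSD2 at -3.64 ± 0.19, and trophoblast genes had 2 of 16 up and 3 down (adjusted p = 0.00386, 0.039 with an estimated correlation). Endothelial genes had 7 of 31 down and 1 up (adjusted p = 0.0413, and 0.0648 with an estimated correlation), and core pluripotency 6 of 24 up and 1 down (adjusted p = 0.0754). CRABP1, SCG2 and PRRX1 were at least 842-fold, 252-fold and 217-fold higher, beside SLC4A4 (8.48 ± 0.26) and CXCR4 (6.63 ± 0.31). C1QTNF6 (-7.35 ± 0.12), FBLN2 (-7.32 ± 0.078), FOSB (-6.70 ± 0.22), KCNQ1 (-6.56 ± 0.21) and VIP (-6.24 ± 0.052) were lower.

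Hyrax Pla6T was set against hyrax fibroblasts for the same question in another species, with 3812 genes up and 3639 down of 14728. POU5F1, SOX2 and LIN28B were at least 38.5-fold, 25.2-fold and 72.1-fold higher and LIN28A rose by 10.61 ± 0.17, to 231 ± 4.1 CPM. KLF4 (-1.25 ± 0.096) and MYC (-2.66 ± 0.12) fell, and NANOG (0.56 ± 0.6, adjusted p = 0.397) was not called. Core pluripotency genes rose in 20 of 21 (adjusted p = 6.51e-14), with UTF1, ZFP42 and TERT at least 2140-fold, 802-fold and 225-fold higher, and EPCAM at a ratio of 4280 (1180 to 35400). Epithelial genes rose in 19 of 20 (adjusted p = 8.4e-23), ESRP1 at least 259-fold, ST14 at a ratio of 1940 (348 to 76700) and the desmosomal DSP by 8.04 ± 0.083. Fibroblast and mesenchymal genes fell in 26 of 29 and rose in 1 (adjusted p = 5.84e-61), DCN at -13.26 ± 0.075, LUM with a ratio of 8620 (2390 to 71200) and POSTN at least 296-fold. Targets of TGF-beta and YAP fell in 11 of 13 and rose in 2 (adjusted p = 1.84e-21), among them TGFBI (-7.55 ± 0.083). E2F and cell cycle genes rose in 18 of 32 and fell in 2 (adjusted p = 0.000331), with CDT1 (2.23 ± 0.099), TK1 (1.98 ± 0.092) and MYBL2 (1.80 ± 0.046). None of the hyrax list calls held with an estimated correlation, where adjusted p ran from 0.172 to 0.856 over the 21 lists.

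Senescence genes fell in hyrax in 10 of 12 and rose in 1 (adjusted p = 4.83e-09, and 0.212 with an estimated correlation), with CXCL8, MMP3 and MMP1 at least 338-fold, 238-fold and 116-fold lower and IGFBP5 at -8.89 ± 0.14. WNT targets rose in 11 of 14 and fell in 1 (adjusted p = 2.66e-05, and 0.176 with an estimated correlation), trophoblast in 8 of 10 with 2 down (adjusted p = 0.00173, and 0.212 with an estimated correlation), and endoderm in 8 of 9 (adjusted p = 0.00227, and 0.326 with an estimated correlation). Primed pluripotency had 8 of 11 up and 2 down (adjusted p = 0.0281, and 0.348 with an estimated correlation), and endothelial genes 16 of 28 up and 6 down (adjusted p = 0.0556). DNMT3B (3.44 ± 0.11) rose, and SOX17, CDX2, CDX1, BMP7 and GPC3 were at least 1030-fold, 530-fold, 4230-fold, 4370-fold and 3870-fold higher. KCNJ15, MMP12, CXCL6, FAM217B and HSPB7 were at least 1850-fold, 1420-fold, 952-fold, 895-fold and 717-fold lower.

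How far both species changed alike was asked over 11646 genes that share a symbol and were tested in both. Across genes, which are not independent replicates, the log2 changes of elephant iPSC against endothelial and of hyrax iPSC against fibroblasts had Spearman's rho of 0.32. In both species 1068 genes rose (500 expected if unrelated), 884 fell in both (479 expected), and 702 went opposite ways (979 expected). Over the 2654 genes called in both, rho was 0.473, and over 7771 genes above 10 CPM in both it was 0.32. C1 lines gave rho 0.271 with 1096 genes up in both (559 expected), C2 lines 0.331 with 1225 (582 expected), and pre-iPSC 0.26. The untreated cells of the species are labelled as different types, endothelial in elephant and fibroblast in hyrax, so shared change may include loss of what both had in common.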

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

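The tests on sequencing depth, on mixed cells, on a carried-over state and on gene models were chosen only after the results were seen. So was the test on the share of the interferon difference that lies between the untreated cultures. Culture and construct were considered then as well, but could not be tested. The tests on fibroblasts in place of endothelial cells, on 1 deviating library and on other splits of the samples were written before.

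The response of C1 and of C2 lines to reprogramming differed by an interaction term, which singled out 6178 genes called for the difference itself. The endothelial list (adjusted p = 0.0403 with an estimated correlation) and the interferon response list (0.00928) differed, and so did KLF4 (4.15) and MYC (2.14) in log2 units. Both lists also differed between the untreated cultures, and how much of the endothelial difference lies there was not tested. At the upper end edgeR's adjusted p was 3.04e-10 for TAC1, 1.73e-14 for IL33, 2.23e-05 for FABP4, 8.07e-05 for FOXA1 and 2.11e-16 for PENK. At the lower end it was 3.62e-20 for SLC7A3, 3.79e-17 for NR0B1, 0.000278 for MPZL2, 1.09e-07 for VSIG2 and 1.5e-05 for FOLR1. FABP4 and FOXA1 lost their call without emEC2 1 (fitted changes 14.14 and 14.15), and MPZL2 without emEC1 2 (-14.38), since the culture then held 0 counts.

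Core pluripotency genes were lower in the C1 than in the C2 T antigen lines. Lower sequencing depth is excluded, since the C1 libraries held 1.04 times the counts of the C2 libraries. A small share of C2-like cells among others would keep 1 ratio of C1 to C2 for all genes. Delivered factors were left out of this test, as their counts can include transgene reads in the lines that carried them. Of the 4 other genes compared, ZSCAN10 stood at 0.348% (0.227 to 0.511), on 26 counts in C1. The other 3 lay below it, ZFP42, UTF1 and PRDM14 at 0 with upper limits of 0.0135, 0.0354 and 0.15%. A share within the limit of ZFP42 is too small for the counts of ZSCAN10. Under other cutoffs for the genes compared, 1 to 10 genes lay below the highest ratio, and 3 or more did in 9 of 16 cases. A state carried over from the chemical step and the culture of origin or factor construct cannot be told apart from one another. Of the genes, 95.2% were under 10 CPM in pre-iPSC but 90.5% also in emEC1. By their library names C1 and C2 lines share no construct and no culture, which the design fixed and no test measured. Both explanations remain open, as does a biological effect of the chemical step itself, which was not tested.

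The untreated endothelial cultures had fibroblast-type levels, with 28 and 27 of 29 mesenchymal genes at 10 CPM or more in emEC1 and emEC2 and 28 in hyrax fibroblasts. Among 27 endothelial genes 7 reached 10 CPM in either culture against 5 in the fibroblasts, a difference of 2, so fibroblasts in place of endothelial cells may or may not account for it. Some endothelial genes were well above this in emEC1 and emEC2: THBD (294 and 233 CPM), LMO2 (223 and 125), PECAM1 (93.5 and 35.2) and EMCN (48 and 28.1). In the elephant list 17 genes lay under 5 CPM in both cultures. Gene models that take no reads are excluded for CDH5, KDR, MMRN2 and ECSCR, the 4 low endothelial genes that reach 10 CPM in another elephant group. The 13 others stay under 10 CPM in every elephant group. Of these, 13 of 13 had at least 20 counts in some elephant group, from 30 for LYVE1 to 455 for SOX17. Only genes past the low-count filter entered this test. It could thus hardly have come out otherwise and excludes nothing. Gene models that take only part of the reads stay open for these 13, as a gene at low level would look alike. Apart from the cell type, no biological explanation was tested, since the design names none.

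Interferon response genes made up part of the difference in response. The mean log2 difference of the list was -5.1, of which 82.8% came from emEC1 against emEC2 (4.23), not far above the bound set for this test, and the C1 against C2 lines differed by -0.877. A candidate explanation is therefore a difference between the untreated cultures rather than between the lines. A single deviating emEC1 library is excluded, as the list mean without either was 4.22 and 4.21. Whether the cultures differ by origin or by handling was not tested.

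Other splits of the same samples were counted as well. For C1 against C2 T antigen lines the real split gave 6416 genes and the highest of the other 34 gave 0, so 1 of 35 splits gave as many. The 2 libraries of a line may not be separate cultures, however, and just 3 of these splits keep the lines whole, too few for a share under 0.05. For OSKMNL against OSKM in C1 the lines also allow 3 splits, too few as well. There 2 of 35 gave as many, 1 gene in the real split and 484 in the highest other. That other split follows a further difference among the C1 lines, a structure of the samples, and the fit that accounts for it called 71 genes. For iPSC against endothelial 2 of 28 splits of the lines gave as many, 3109 genes in the real one and 3148 in the highest other, so this count alone does not exclude chance. That other split sets the C2 lines apart from the C1 lines and endothelial cultures, a structure of the samples, and the remaining 26 gave 0 genes. The C1 and C2 comparisons share no library and had 1923 genes up in both (874 expected if unrelated) and 1712 down in both (625 expected). The untreated cultures were alike (r = 0.968 across genes), so other cells set against them may share changes for that reason. The overlap therefore does not settle whether chance is excluded.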

How the results depend on the processing

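Leaving out the whole line Eem6TH was an alternative chosen after the data were seen. Size factors (RLE), DESeq2 and, where it could be fitted, a replicate block left every count of called genes within 1.5 times its value. DESeq2 gave 6569 genes for iPSC against endothelial, 105 for OSKMNL against OSKM in C1, 948 for OSKMNL against OSKM in C2 and 7101 for C1 against C2 T antigen lines. It gave 6530 for the difference in response, 2672 for the endothelial cultures, 6596 for pre-iPSC against endothelial, 2166 for C1 iPSC against pre-iPSC and 7223 for hyrax. Of 677 calls on named genes 656 kept their side under DESeq2, 675 under RLE, 672 without a filter and 619 of 628 under the block, with 0 changes of sign under DESeq2. Without the line Eem6TH 7122 genes were called for C1 against C2 and 6086 for the difference in response. Fitted on C1 libraries only, OSKMNL against OSKM gave 51 genes.

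With the replicate block the counts were 6191, 51, 7056, 6021, 2562, 6539, 2134 and 7330, in the order above without OSKMNL against OSKM in C2. That block could not be fitted, since the columns of Eem6TH are not numbered. For the same reason 6191, 7056 and 6021 come from fits that also left out Eem6TH, so they do not show the block alone. The numbers do not pair the samples.

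Dropping the fold minimum raised every count, as more genes can pass: 13045 for iPSC against endothelial, 1635 and 4635 for OSKMNL against OSKM in C1 and C2. It gave 14099 for C1 against C2, 10947 for the difference in response, 8734 for the endothelial cultures, 12624 and 8731 for pre-iPSC against endothelial and against C1 iPSC, and 12238 for hyrax. Per line it gave 12200 in Ela6T, 12185 in Ela6sh, 12103 in Ela4T, 11971 in Ela4sh, 12666 in Eem4TH and 12777 in Eem6TH. Without the filter on low counts 121 genes were called for OSKMNL against OSKM in C1, and the cause was not tested. Counts summed per line gave 3109 genes for iPSC against endothelial, a fit with 1 value per line and so fewer samples. OSKMNL against OSKM gave 215 genes for Ela6T against Ela4T and 4 for Ela6sh against Ela4sh, each from fewer samples. With an estimated correlation 30 of 231 list tests passed, against 76 at the preset one. Over genes called in both species rho was 0.473, the alternative having kept only called genes.

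Leaving out 1 library at a time gave 45 to 121 genes for OSKMNL against OSKM in C1 (without Ela6sh 1 and Ela6T 1). Over all named genes 5410 of 5597 calls were kept, 185 were lost, and 6 changes of sign occurred. Of those, NANOG ran from -0.12 to 1.45 in the difference in response. For SOX2 in OSKMNL against OSKM in C1 the range was -0.24 to 1.78. In C1 iPSC against pre-iPSC it was -4.87 to 0.71 for UTF1 and -3.06 to 2.51 for ANKRD1. These genes lay near the floor in a compared group; the cause was not tested.

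Pooled over 6 lines, KLF4 had a value near 0 in iPSC against endothelial and changed sign with the lines. KLF4 was -0.23 without Ela6T, -0.16 without Ela6sh, -0.30 without Ela4T, -0.23 without Ela4sh and -2.62 in C2 alone. NR0B1 was 2.32 with counts summed and 8.72 in C2 alone, and LAPTM5 0.12 with counts summed. VRTN (-0.90) and DNMT3B (-0.50) changed sign in C1 alone, and E2F2 (-1.22), IGFBP5 (-0.061) and IFI44L (1.80) in C2 alone, so the pooled values of these genes average lines that differ. For Ela6T against Ela4T MYC was 0.051, and for Ela6sh against Ela4sh SOX2 was -0.48 and RAB25 -0.24. In pre-iPSC TUBB3 was 0.70 against emEC1 alone, and MYC 0.15 and NANOG -0.28 against emEC2 alone; the cause was not tested.

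Scaling moved the median of all genes in iPSC against endothelial, which was 0.57 without scaling, 0.07 with TMM and 0.096 with RLE. In Eem6TH against emEC2 it was 0.12 with TMM and 0.18 with RLE, and in Eem4TH 0.097 and 0.15, so changes smaller than these have no secure direction. Depth limits the genes near the floor: bounds against a group at 0 counts rest on 3 counts, and changes in SOX2, NANOG and POU5F1 in Ela4sh and Ela6sh rest on few counts.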

Other observations

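Lists of mucosal epithelium, HOX and imprinted genes were chosen after their levels were seen, and all values here are descriptions. Of 20 mucosal genes 13 reached 10 CPM in each C1 line and in pre-iPSC, 2 in the C2 lines and 0 in the endothelial cultures. Of these 20, 19 were called higher in C1 lines against emEC1, 20 in pre-iPSC, 8 in C2 lines and 16 in C1 over C2 T antigen lines. Of 35 HOX genes 15 to 16 reached 10 CPM in C1 lines, 12 in pre-iPSC, 11 and 10 in emEC1 and emEC2 and 1 in C2 lines. In C2 lines 28 of 34 HOX genes were lower and 2 higher than in emEC2, while in C1 lines 13 were higher and 8 lower than in emEC1. Of 16 imprinted genes 6 reached 10 CPM in C1 lines, 9 in C2 lines, 7 in pre-iPSC, and 11 and 10 in the endothelial cultures.

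The chi-square per degree of freedom between the libraries of a line was 24.3 for Ela6T, 9.81 for emEC2, 5.58 for Eem4TH and 3.15 to 3.86 in the other elephant lines, where counting error alone gives about 1. By the correlation of log2 counts within a line the order differed: Ela6T had 0.9884, above Pla6T (0.9867) and Eem4TH (0.9818). Leaving out Ela6T 1 raised the count of genes called for OSKMNL against OSKM in C1 from 71 to 121.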
